A study of Escherichia coli str. K-12 substr. MG1655 with 2 samples.

How the data were processed

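RNA that copurified with the MS2 coat protein was sequenced from 2 cultures of Escherichia coli K-12 MG1655 carrying rne131, an allele that truncates the endoribonuclease RNase E and removes the part on which the RNA degradosome assembles. The method, MS2-affinity purification coupled with RNA sequencing, holds an RNA tagged with the MS2 aptamer on a column through a fusion of the MS2 coat protein and maltose-binding protein, and the RNAs that come with it are eluted with maltose. Per the labels' protocols, the aptamer library came from cells expressing the aptamer joined to the terminator of the small RNA RyhB, and the control library from cells with the empty vector. Per the labels' protocols, arabinose at 0.1% was given for 10 min, lysates were passed over amylose resin carrying the fusion protein, the eluted RNA was treated with DNase, and cDNA libraries were made with a ScriptSeq kit. The labels name both exponential phase (OD600 of 0.5) and stationary phase (OD600 of 1) for each library, and whether cells of both phases were pooled is not given in the sources used here.

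The deposited table holds read counts per feature for both libraries, per the file headers. It lists 7379 features, which are 4293 genes, 3085 intergenic regions named by their flanking genes, and the replication origin. Bowtie is named in the submitters' processing notes, without a version or a role. The genome build, the annotation, the rule for counting reads on strands and the treatment of reads with several matches are not given in the sources used here. The lowest count is 1 in both libraries, with 625 features at 1 in the aptamer library and 1470 in the empty vector library, so a feature without reads cannot be told from a feature with 1 read. Whether 0 was set to 1 or 1 read was added to every feature is not given in the sources used here, and the counts were used as deposited. Beside the counts, the authors deposited a normalized value per feature and the ratio of the normalized values, per the file headers. Dividing each count by its normalized value gave the same library total for all features, 5084634 reads for the aptamer library and 5475017 for the empty vector library. The deposited ratio differed from the ratio of counts scaled by these totals by at most 6.59e-06 percent. The features listed held 4551946 reads (89.5% of the total) in the aptamer library and 5112592 reads (93.4%) in the empty vector library. No column of values was left unused.

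With 1 library per group there was no test of a difference, and no p-value is given. Each gene is described by the ratio of RPM (reads scaled by the library totals above, aptamer over empty vector) with an exact conditional (Clopper-Pearson) 95% interval. The interval covers counting error only, because PCR copies without molecular identifiers are not independent molecules and because it holds no spread between cultures. Genes with at least 20 reads in both libraries together entered the counts of genes. A ratio of 4 was the size counted, and log2 ratios used a pseudocount of 0.5 reads. Gene lists were described by the median log2 ratio of their members and its percentile among 10000 random lists of the same size, drawn within 10 classes of mean expression. Such a percentile describes these libraries only. A common scaling factor shifts a list and its random lists by the same amount.

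The ratios, intervals and list percentiles to be computed, the rule for named genes, 20 gene lists and the first group of alternatives below were set before the data were examined. The named genes were the 12 highest and the 12 lowest by the interval bound nearest to 1, the 5 most abundant genes of each library, the highest, lowest and most abundant member of each list, and rne, hfq and araC. The most abundant member of a list is that with the highest sum of RPM over both libraries, so another member can lead in a single library. A further 7 lists (5 operons, Hfq-binding small RNAs and stable RNAs not known to need Hfq) were made after the values had been seen. Gene symbols are those of the deposited table. Of the 4293 genes, 4273 matched a symbol or synonym in the RefSeq gene table of assembly ASM584v2 and 20 did not. In 3 cases a pair of names (ade and purE, gtrA and hemA, waaJ and waaR) matched the same entry, so 3 of these matches are doubtful, and their values rest on the names in the deposited table. That table was used only for gene classes, for names and for which genes neighbour each other. No coordinates are given, because the build behind the counts is not known.

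The alternatives set in advance were trimmed mean of M-values (TMM) scaling from edgeR, median-of-ratios scaling, totals without rRNA and tRNA genes, a minimum of 100 reads, no minimum, a pseudocount of 5, a ratio of 2, an interval bound of 4, and shares without rRNA. Scaling by the sum of the listed features, totals without rRNA genes and the 10 most abundant other features of each library, lists with 1 gene per run of neighbours, and 1 read less in every feature were added after the data had been seen. The gene kept for a run was its most abundant over both libraries together, so medians and percentiles of such lists depend on that choice. edgeR 4.0.16 in R 4.3.3 supplied the TMM factors and no test. All else was computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plotted with matplotlib 3.10.9.

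The calculation was tested on simulated counts for all 4293 genes at the depths of the aptamer and empty vector libraries. Of 100 genes made 8-fold higher, 94% passed a ratio of 4 and 95% of the intervals held the true ratio. For 100 genes made 8-fold lower these values were 98% and 93%. None of the 2654 unchanged genes passed a ratio of 4, and 96.2% of their intervals held the true value. These values check the calculation only. They give no rate of false calls for the deposited counts, where the effect of PCR copies and the spread between cultures are not known. Of 100 random lists, 4% fell outside the range from the 2.5 to the 97.5 percentile. Those lists were drawn from simulated values in shuffled order, without the likeness of neighbouring genes that the data have.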

Results

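The RNA that copurified with the MS2 coat protein was compared between a culture expressing the MS2 aptamer joined to the RyhB terminator and a culture with the empty vector, both in the rne131 background. The comparison asks which RNAs were more or less abundant in the eluate with the bare aptamer, which carries no small RNA body, than without it. No library of RNA taken before the column was available. A ratio therefore cannot tell retention on the column from transcript level in the cultures, and this holds for every gene and list below. There was 1 library per group, so no difference reported here has a replicate check. The aptamer library held 5084634 reads and the empty vector library 5475017, so that 1 read was worth 0.197 and 0.183 RPM, the reads of a feature scaled to a common library total. Genes had a median of 22 reads in the aptamer library and 15 in the empty vector library.

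Ribosomal RNA made up most of both libraries. The 22 rRNA genes took 74.1% of the reads in the aptamer library (Clopper-Pearson 95% interval 74.1 to 74.2) and 74.6% in the empty vector library (74.5 to 74.6). The 5 most abundant genes were the same in both, the 23S rRNA genes rrlB, rrlE, rrlC, rrlA and rrlH, with ratios of 0.982, 1.00, 1.00, 1.00 and 1.00, which lay below 1 with TMM and median-of-ratios scaling and above 1 with totals without rRNA and tRNA. With 583043 reads in the aptamer library and 639360 in the empty vector library, rrlB was the most abundant of them. 16S rRNA genes held 18.5% of the aptamer library and 20.9% of the empty vector library, and 5S rRNA genes 0.215% and 0.0731%. Within the list of rRNA genes the lowest ratio was that of the 16S gene rrsE, 0.855 (0.849 to 0.860), which lay above 1 with totals without rRNA and tRNA, and the highest that of the 5S gene rrfG, 12.9 (3.21 to 113), from 24 and 2 reads. Copies of an rRNA gene are nearly identical, so the assignment of reads to single copies is uncertain. The median ratio of the list was 1.68, at the 91.1 percentile of random lists, with 10 genes at least 2-fold higher, and it fell to a log2 value of -0.0218 with TMM scaling. With 1 gene per run of neighbours, an alternative added after the data had been seen, the rRNA median ratio was 1.00, at the 42.9 percentile. Keeping the most abundant gene of a run favours 23S over 5S genes, so this median lies near the 23S ratios above.

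The genes that stood highest in the aptamer library included several of lipopolysaccharide core synthesis. The 12 genes with the highest interval bounds were waaU, bssS, waaJ, arcZ, yibB, yfeC, rplQ, yiaG, mglB, waaS, ytfQ and yciM. The core-synthesis gene waaU had 304 reads in the aptamer library and 2 in the empty vector library, a ratio of 164 (44.9 to 1358). In the same operon, waaJ had 334 and 3 reads, a ratio of 120 (40.7 to 584), and waaS 279 and 7 reads, a ratio of 42.9 (20.6 to 108). The biofilm regulator gene bssS had 420 and 4 reads, a ratio of 113 (43.8 to 417). ArcZ, an Hfq-dependent small RNA that activates translation of the stationary phase sigma factor RpoS, had 471 and 6 reads, a ratio of 84.5 (38.5 to 232). The most abundant of the 12 was rplQ, for ribosomal protein L17, with 6511 and 263 reads and a ratio of 26.7 (23.6 to 30.3). The genes for the galactose-binding protein MglB and the sugar-binding protein YtfQ had ratios of 29.2 (22.7 to 38.1) and 28.6 (19.6 to 43.3). The ratios of yibB, yfeC, yiaG and yciM were 103, 79.0, 55.6 and 32.7.

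The genes that stood lowest in the aptamer library were abundant in the empty vector library and in part adjacent to each other. dmsD, for a chaperone of dimethyl sulfoxide reductase, had 151 reads in the aptamer library and 12359 in the empty vector library, 76.0-fold lower (64.7 to 89.8), and ynfH beside it was 72.5-fold lower (58.4 to 91.0). rpsB, for ribosomal protein S2, had 1966 and 116139 reads, 54.9-fold lower (52.5 to 57.4). The small RNA gene tff, which lies next to rpsB, was 42.2-fold lower (37.0 to 48.3). The region between tff and rpsB was 43.7-fold lower (37.9 to 50.8), so reads of tff may belong to an rpsB transcript. The genes for ribosomal proteins L3 and L4, rplC and rplD, were 37.3-fold (35.6 to 39.0) and 24.0-fold lower (22.8 to 25.4). atpG, for the gamma subunit of ATP synthase, was 28.6-fold lower (26.6 to 30.7), and the RNA helicase gene deaD 27.2-fold lower (22.8 to 32.8). The remaining genes of the lowest 12 were frlB, ygbJ, fsr and yphB, which were 92.2-, 58.7-, 43.2- and 31.7-fold lower, with 397, 253, 512 and 1059 reads in the empty vector library. Reads were more concentrated in the empty vector library, where the 10 most abundant genes other than rRNA held 44.9% of the reads of such genes, against 27.8% in the aptamer library.

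**Figure D1:**
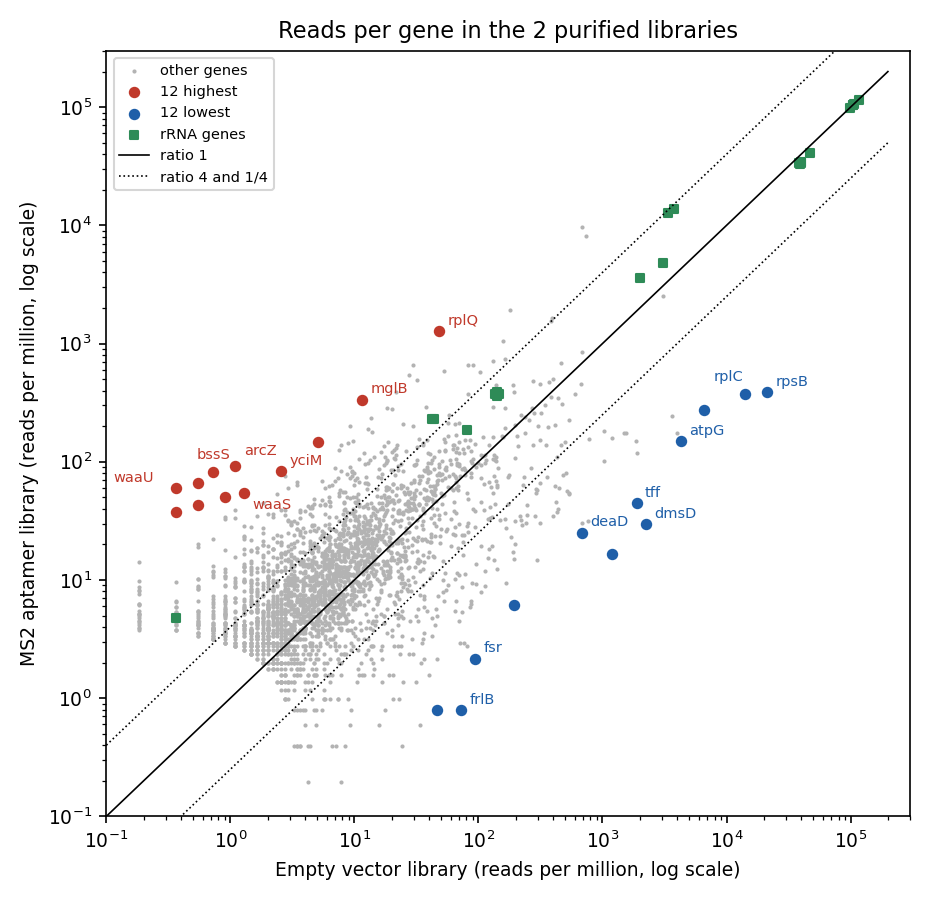
RPM of each gene in the empty vector library (horizontal, log scale) and in the MS2 aptamer library (vertical, log scale), each point a gene with 20 or more reads in both libraries together. The 12 highest genes (red) lie above the dotted line of ratio 4, the 12 lowest (blue) below the dotted line of its inverse, and the most abundant rRNA genes (green squares) near the line of ratio 1.

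Of 2846 genes with 20 or more reads, 523 (18.4%) were 4-fold or more higher in the aptamer library and 200 (7.03%) were 4-fold or more lower, while 1288 (45.3%) lay within 2-fold. The interval itself lay beyond 4-fold for 234 of the higher and 134 of the lower genes. The log2 ratio had a median of 0.67 (a ratio of 1.59), an interquartile range of 1.79 and an SD of 1.69 across genes. Higher genes made up 72.3% of those past 4-fold, but 44.6% with TMM scaling (269 higher, 334 lower), 45.2% with median-of-ratios scaling (271 and 329) and 78.3% with totals without rRNA and tRNA (644 and 178). These scalings moved the median of all genes by -0.77, -0.74 and 0.29 on the log2 scale. Taken relative to the median of all genes, 275 genes lay 4-fold or more above it and 311 lay 4-fold or more below it.

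RpoS-dependent genes of stationary phase stood high as a group. Of 23 members measured, 16 were at least 2-fold higher in the aptamer library, 3 at least 2-fold lower and 4 within 2-fold, with a median ratio of 3.10 at the 99.8 percentile of random lists (98.6 with 1 gene per run of neighbours). The morphogene bolA had a ratio of 20.4 (12.4 to 36.1). Against the group, dps, for the DNA-protecting protein of starved cells, was 5.70-fold lower (5.32 to 6.12), and osmF 8.09-fold lower (4.64 to 15.2). Over both libraries together dps was the most abundant member. Targets of RyhB, which represses mRNAs of iron-using proteins, had a median ratio of 2.76 at the 99.2 percentile, with 16 of 22 members at least 2-fold higher and 2 at least 2-fold lower. Several of these targets share operons, and with 1 gene per run of neighbours the percentile was 93.4. The iron superoxide dismutase gene sodB had 3637 and 721 reads, a ratio of 5.43 (5.01 to 5.89), msrB had a ratio of 16.2 (5.19 to 81.3), and the siderophore receptor gene cirA was 3.05-fold lower (1.27 to 8.42).

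Transfer RNA genes as a whole did not stand apart, but the glyW-cysT-leuZ operon, whose 3′ external transcribed spacer is known to bind small RNAs, lay near the upper end. All 3 of its genes were at least 2-fold higher, with a median ratio of 5.38 at the 96.7 percentile. They form 1 run of neighbours and are not independent, and leuZ alone lay at the 97.7 percentile. Together they had only 104 reads in the aptamer library and 16 in the empty vector library. leuZ had 66 reads in the aptamer library and 7 in the empty vector library, a ratio of 10.2 (4.66 to 26.2), the highest of all tRNA genes measured, and cysT had a ratio of 3.77 (1.47 to 11.4). Over 55 tRNA genes the median ratio was 1.43, at the 13.9 percentile, with 17 at least 2-fold higher and 3 lower, and the median fell below 1 with TMM and median-of-ratios scaling. The ratio of argX was 0.300 (0.144 to 0.580). That of leuW, the most abundant tRNA gene over both libraries together, was 1.56 (1.15 to 2.14) and also fell below 1 with those scalings. Small RNAs known to bind Hfq or to regulate other RNAs had a median ratio of 1.46 at the 33.8 percentile, below 1 with the same scalings. Of 23 measured, 8 were at least 2-fold higher and 2 at least 2-fold lower. They ran from arcZ at the top to tff, whose reads may belong to an rpsB transcript, at the bottom. Among the 4 housekeeping RNAs, tmRNA (ssrA) was 5.02-fold lower (4.65 to 5.43) and the signal recognition particle RNA (ffs) 5.51-fold higher (4.45 to 6.89). The other 2 differed by at least 2-fold in opposite directions, and the median ratio of 0.933 was at the 35.8 percentile and rose above 1 with totals without rRNA and tRNA.

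Targets of RybB and MicA, mostly mRNAs of outer membrane proteins, had a median ratio of 2.36 at the 94.0 percentile. Of 14 measured, 9 were at least 2-fold higher and 1 lower. The higher ones include rluD (3.79) and phoP (2.65), which do not code for outer membrane proteins. The porin gene ompW had 3320 and 163 reads, a ratio of 21.9 (18.7 to 25.8), whereas tolC was 8.25-fold lower (7.06 to 9.69). The most abundant member, ompA, had a ratio of 0.819 (0.801 to 0.838), which turned to a log2 value of 0.00384 with totals without rRNA and tRNA. For targets of DsrA, RprA and ArcZ the median ratio was 1.49 at the 48.6 percentile, below 1 with TMM and median-of-ratios scaling, with 3 of 8 at least 2-fold higher. The nucleoid protein gene hns had a ratio of 5.49 (4.42 to 6.89), rpoS 1.92 (1.69 to 2.18) and tpx 0.589 (0.361 to 0.944).

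Genes for RNA decay and RNA-binding proteins had a median ratio of 1.53 at the 49.1 percentile, below 1 with TMM and median-of-ratios scaling, with 5 of 16 at least 2-fold higher and 1 lower. The mRNA of hfq, the RNA chaperone of many small RNAs, had 3334 and 447 reads, a ratio of 8.03 (7.27 to 8.88). rppH, for the RNA pyrophosphohydrolase that starts decay from the 5′ end, had a ratio of 12.6 (8.69 to 19.0). The RNase E inhibitor gene rraA was 2.53-fold lower (1.94 to 3.31). RNase E itself, truncated in this strain, had 582 and 737 reads of rne, a ratio of 0.850 (0.761 to 0.949), which turned to a log2 value of 0.0576 with totals without rRNA and tRNA.

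Ribosomal protein genes spread widely around a median ratio of 1.10 at the 15.9 percentile. Of 53 measured, 12 were at least 2-fold higher and 7 at least 2-fold lower, and the median fell below 1 with TMM and median-of-ratios scaling. The highest was rplQ, and rpsB was the lowest and, over both libraries together, the most abundant. Cold shock genes had a median ratio of 1.44 at the 38.2 percentile, also below 1 with those scalings, with 5 of 14 at least 2-fold higher and 3 lower. Among them deaD was the lowest and, over both libraries together, the most abundant. The iron-sulfur chaperone gene hscB was the highest, with a ratio of 8.23 (4.70 to 15.6). Heat shock genes had a median ratio of 1.96 at the 72.9 percentile, with 7 of 14 at least 2-fold higher. The chaperonin gene groS had a ratio of 4.26 (3.09 to 5.98), and ibpB, for a small heat shock protein, was 3.82-fold lower (3.23 to 4.54).

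The 10 genes of the arabinose regulon, whose inducer was given to both cultures, had a median ratio of 0.980 at the 36.1 percentile, with 9 within 2-fold and 1 higher, and the median lay above 1 with totals without rRNA and tRNA. The isomerase gene araA, the most abundant, had a ratio of 0.864 (0.807 to 0.925), which also lay above 1 with those totals. araG had a ratio of 0.506 (0.462 to 0.553) and araJ of 2.83 (2.42 to 3.32). The regulator gene araC, which is also carried by many arabinose-inducible plasmids, had a ratio of 0.800 (0.716 to 0.893) and was the sole gene with 20 reads in the list of lac and plasmid marker genes, at the 37.7 percentile. The maltose regulon had a median ratio of 1.38 at the 33.1 percentile, below 1 with TMM and median-of-ratios scaling, with 5 of 13 at least 2-fold higher and 1 lower. With 1 gene per run of neighbours, which leaves 4 genes, its median ratio was 3.35 at the 92.3 percentile. malQ, its most abundant gene over both libraries together, was 2.29-fold lower (1.96 to 2.68), and malZ had a ratio of 7.66 (3.79 to 17.5).

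Flagellar and chemotaxis genes had the lowest median of the 20 lists set in advance. With 1 gene per run of neighbours, however, the Fur regulon (a ratio of 0.533) and, narrowly, the arabinose regulon (0.760) were lower. Without a minimum of reads the flagellar median turned to a log2 value of 0.11. Of 48 flagellar and chemotaxis genes in the deposited table, only 11 had 20 or more reads, and the values here describe those. Of these, 7 were at least 2-fold lower and 3 higher, with a median ratio of 0.372 that lay below all 10000 random lists. With 1 gene per run of neighbours the median ratio was 0.761, at the 1.29 percentile. The motor gene motB, the most abundant over both libraries together, was 11.8-fold lower (6.54 to 23.3). fliP was 39.9-fold lower (6.79 to 1614) from 1 and 43 reads, and flgN had a ratio of 11.2 (5.68 to 25.4). The Fur regulon of iron uptake had a median ratio of 0.958 at the 2.34 percentile (0.67 with 1 gene per run of neighbours), with 5 of 14 at least 2-fold higher and 3 lower, and the log2 median rose above 0 with totals without rRNA and tRNA (0.23) and without a minimum of reads (0.33). The ferrous iron transporter gene feoB, the most abundant over both libraries together, was 2.23-fold lower (1.62 to 3.11). The lowest was cirA, and the iron-sulfur assembly gene sufA had 32 and 1 reads, a ratio of 34.5 (5.76 to 1403).

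Cryptic prophage genes had a median ratio of 2.43 at the 92.8 percentile, with 10 of 14 at least 2-fold higher and 1 lower, and lay at the 99.3 percentile with 1 gene per run of neighbours. The integrase gene intR had 22 and 1 reads, a ratio of 23.7 (3.83 to 978), borD, the most abundant, 0.579 (0.493 to 0.678), and ydaU 0.453 (0.172 to 1.08). Insertion sequence genes, whose copies share reads, had a median ratio of 1.65 at the 52.0 percentile, with 3 of 7 at least 2-fold higher. The ratios were 8.88 (3.16 to 34.5) for insX, 1.65 (1.31 to 2.09) for insN and 0.560 (0.263 to 1.14) for insQ, and both insN and the list median fell below 1 with TMM and median-of-ratios scaling.

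**Figure D2:**
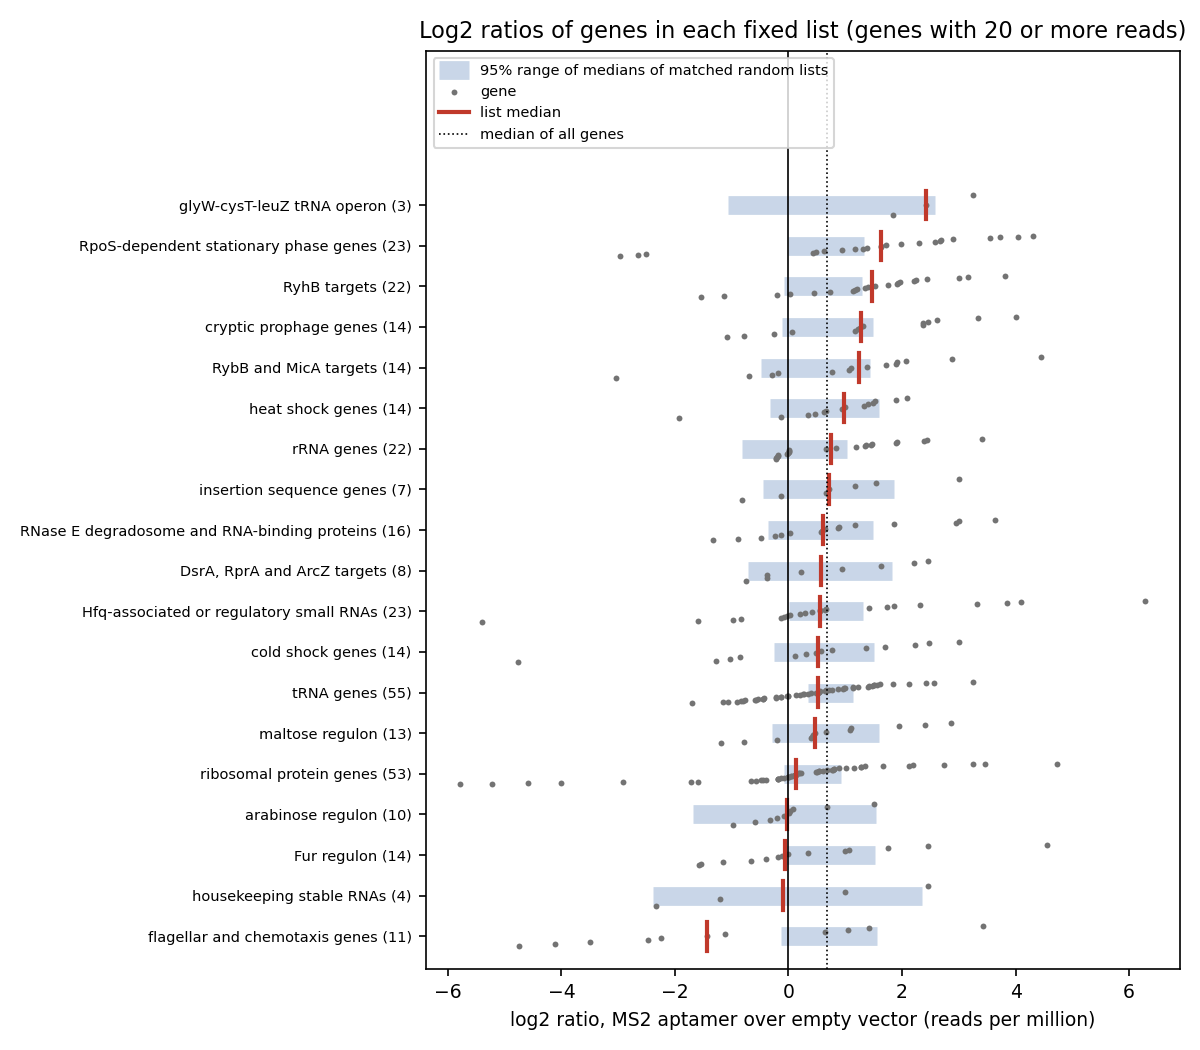
Log2 ratio (aptamer over empty vector, RPM) of each gene with 20 or more reads (grey points) in the 19 lists with 3 or more such genes, which stand in parentheses. The red bars are list medians, the blue bands the 95% range of medians of 10000 matched random lists and the dotted line the median of all genes (0.67), and the medians of RpoS-dependent genes, RyhB targets, flagellar genes and the Fur regulon lie outside their bands.

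Within operons, ratios changed in steps from gene to gene, in 5 operons chosen after their values were seen. In the S10 ribosomal protein operon the ratio was 0.0625 at rpsJ, 0.0268 at rplC, 0.0416 at rplD, 0.133 at rplW and 0.332 at rplB, and then lay between 0.760 at rpsS and 1.16 at rpmC in the genes that follow. rplC held 19.8% of the operon's reads in the aptamer library (19.0 to 20.6) and 56.4% in the empty vector library (56.1 to 56.6). In the ATP synthase operon the ratio went from 4.17 at atpI down to 0.0350 at atpG and back to 0.336 at atpC. The alpha operon was higher throughout, with 4.59 at rpsM, 6.68 at rpsK, 11.0 at rpsD, 14.0 at rpoA and 26.7 at rplQ. Of the 10 waa genes listed in this operon, all had ratios above 3, from 3.60 at waaG to 164 at waaU. Around hfq, the ratio was 7.32 at miaA, 8.03 at hfq, 2.40 at hflX, 0.723 at hflK and 2.12 at hflC.

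**Figure D3:**
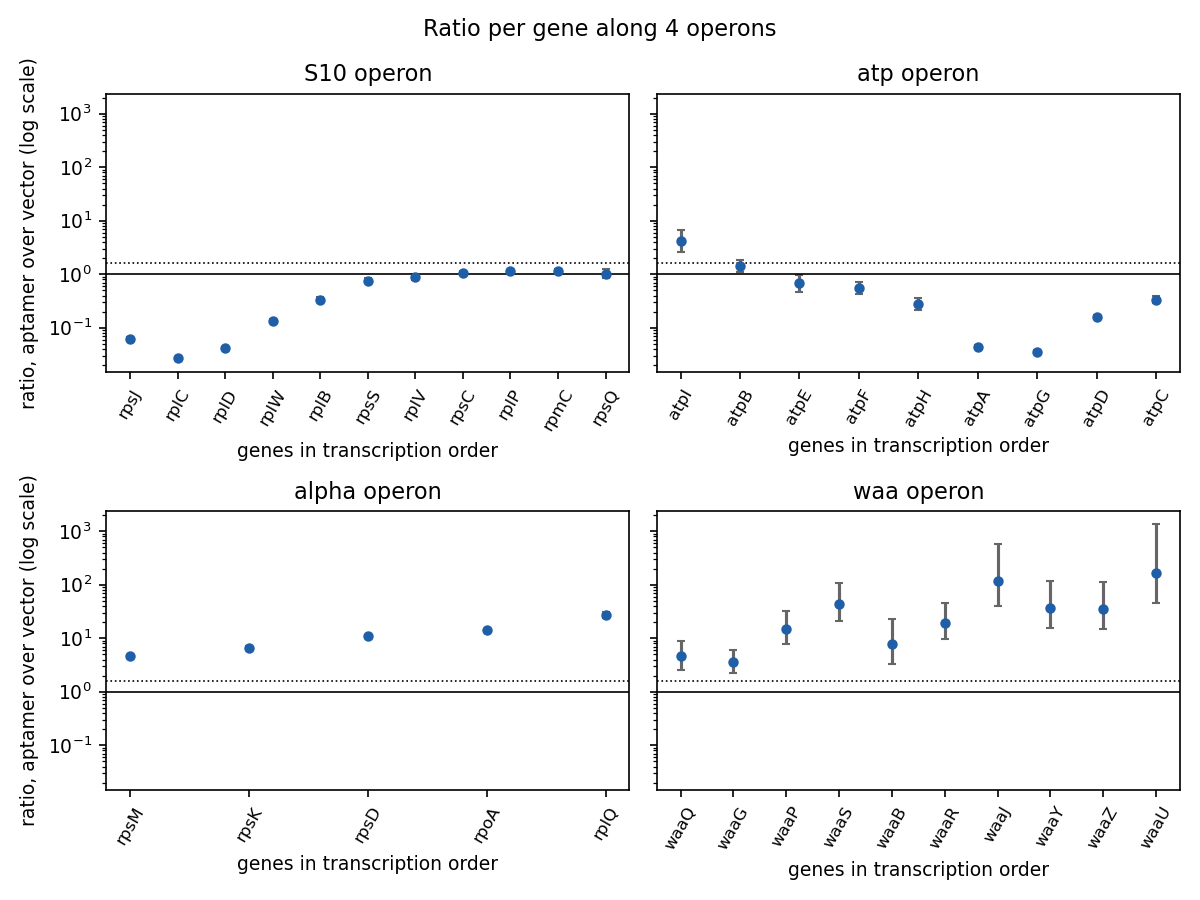
Ratio of RPM (aptamer over empty vector, log scale) of each gene along 4 operons, in the order of transcription, with exact 95% intervals for counting error as bars. The solid line is a ratio of 1 and the dotted line the median ratio of all genes (1.59), and the lowest points are rplC in the S10 operon (0.0268) and atpG in the atp operon (0.0350).

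These ratios describe 2 libraries and not the conditions, and reads of overlapping or antisense genes cannot be separated because the strand rule of the counts is not known. The gene ryhB, whose terminator the aptamer transcript carries, was listed at 1 read in both libraries. Recovery of the aptamer transcript on the column is therefore not shown by these counts. Whether 0 was set to 1 or 1 read was added to every feature is not known, and with 1 read less in every feature, a setting added after the data had been seen, the ratio would be 326 (58.1 to 12929) for waaU, 206 (36.5 to 8165) for yibB, 179 (49.2 to 1487) for waaJ and 24.8 (4.02 to 1020) for rrfG. Genes listed at 1 read in a library, such as sufA, intR and fliP, would then have 0 reads there and no finite ratio.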

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

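The 5 results here are intergenic regions, which entered no comparison of genes, and they were singled out because, among regions with 20 or more reads, the lower bounds of their ratio intervals were the highest. Other regions had higher point ratios than some of these, such as 41.6 between elbB and arcZ. The region between rbsB and rbsK had 5776 reads in the aptamer library and 192 in the empty vector library, a ratio of 32.4 (28.1 to 37.6). The reference gene table places the small RNA gene rbsZ there, while rbsB and rbsK themselves had ratios of 3.01 and 4.67. The region between aspA and fxsA had 1724 and 68 reads, a ratio of 27.3 (21.4 to 35.3), beside a ratio of 10.7 for aspA. Between bssS and dinI the ratio was 49.2 (22.3 to 135), from 274 and 6 reads. Between yiaF and yiaG it was 40.6 (18.3 to 112), from 226 and 6 reads, with ratios of 1.23 for yiaF and 55.6 for yiaG. Between mglA and mglB it was 125 (22.0 to 4976), from 116 and 1 reads, a ratio that rests on the lowest value listed, where 0 and 1 read cannot be told apart. Over 1306 intergenic regions with 20 or more reads, 308 were 4-fold or more higher in the aptamer library and 113 were 4-fold or more lower. No explanation for these regions was weighed.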

How the results depend on the processing

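Scaling by the sum of the listed features, totals without rRNA genes and the 10 most abundant other features, lists with 1 gene per run of neighbours, and 1 read less in every feature were chosen after seeing the data. With no replicates, no library could be left out. No paired analysis was possible because there is 1 library per group. Over all alternatives, 23 of 189 list medians changed sign, in 13 of 19 lists, as did 19 of 643 log2 ratios of single genes, in 11 of 73 genes. Reversals are given below for lists outside the central 95% of random lists and for genes whose interval excludes a ratio of 1. Of list medians that changed sign inside that range, DsrA, RprA and ArcZ targets came to -0.19, cold shock genes to -0.24 and insertion sequence genes to -0.0484 with TMM scaling, and housekeeping RNAs to 0.19 with totals without rRNA and tRNA. A scaling factor shifts all log2 ratios alike by construction; the cause of the other changes was not tested. Low depth limits genes with few reads, since 1 read is the lowest value listed.

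With TMM scaling, 269 genes were 4-fold or more higher and 334 lower. The log2 medians became -0.22 for small RNAs, -0.0218 for rRNA genes, -0.25 for tRNA genes, 1.66 for the glyW-cysT-leuZ operon, 0.70 for RyhB targets, -0.80 for the arabinose regulon, -0.30 for the maltose regulon, 0.20 for heat shock genes, -0.16 for RNA decay and RNA-binding proteins, -0.83 for the Fur regulon, 0.86 for RpoS-dependent genes and -0.64 for ribosomal protein genes. The log2 ratio reversed for rrlC (-0.76), rrlH (-0.76), leuW (-0.13) and insN (-0.0484). Median-of-ratios scaling gave 271 higher and 329 lower genes. The log2 medians became -0.19 for small RNAs, -0.23 for tRNA genes, 1.68 for the glyW-cysT-leuZ operon, 0.72 for RyhB targets, -0.77 for the arabinose regulon, -0.27 for the maltose regulon, 0.23 for heat shock genes, -0.81 for the Fur regulon, 0.89 for RpoS-dependent genes and -0.61 for ribosomal protein genes. It reversed rrlC (-0.74), rrlH (-0.74), leuW (-0.10) and insN (-0.0233).

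With totals without rRNA and tRNA genes, the log2 median was 0.81 for tRNA genes and reversed to 0.23 for the Fur regulon. The log2 ratio reversed for rrlB (0.26), rrsE (0.0645), ompA (0.00384), araA (0.0802) and rne (0.0576). Scaling by the sum of the listed features reversed rrlB (0.0345). A minimum of 100 reads left 248 higher genes, an SD of 1.95, and log2 medians of 0.81 for tRNA genes and -1.36 for the Fur regulon. Without a minimum 848 genes were 4-fold or more higher, and the log2 median reversed to 0.33 for the Fur regulon and 0.11 for flagellar genes. A pseudocount of 5 gave an SD of 1.47 and 1.57 for the glyW-cysT-leuZ operon. A ratio of 2 gave 1165 higher and 393 lower genes, and an interval bound of 4 gave 234 higher genes. With 1 gene per run of neighbours the log2 median was 1.74 for the maltose regulon and -0.91 for the Fur regulon. Without rRNA in the denominator, tRNA genes held 0.303% of the aptamer library and 0.170% of the empty vector library. Small RNA genes, counted here together with the 4 housekeeping RNAs, held 0.780% and 1.76%. The housekeeping RNAs had 3682 reads of this class in the aptamer library and 6385 in the empty vector library. The difference in the class share rests on tff, which held 227 of 6106 reads of the class in the aptamer library and 10305 of 18170 in the empty vector library. Since reads of tff may belong to an rpsB transcript, the class shares do not show a difference in small RNAs. With 1 read less in every feature, 539 genes were 4-fold or more higher and 205 lower.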

Other observations

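The genes, RNAs and tests of this part were chosen after the data had been seen, including the totals without rRNA genes and the 10 most abundant other features; TMM scaling, median-of-ratios scaling and totals without rRNA and tRNA were set in advance. Apart from ArcZ, several small RNAs that bind Hfq were higher in the aptamer library. RydC had 119 reads in the aptamer library and 7 in the empty vector library, a ratio of 18.3 (8.61 to 46.5), and ryjA a ratio of 10.5 (5.30 to 23.8). Spot 42 (spf) had a ratio of 3.67 (2.55 to 5.39) and chiX of 5.38 (2.02 to 18.0), while gcvB (1.15) and fnrS (0.916) were close to 1. Besides fnrS, ratios below 1 were those of glmZ, 0.538 (0.184 to 1.43), of sdsR, 0.359 from 4 and 12 reads, of omrA, 0.359 from 1 and 3 reads, of dsrA, 0.538 from 1 and 2 reads, and of micF, 0.718 from 2 and 3 reads, and the interval of each included 1. RyhB itself was listed at 1 read in both libraries, the lowest value listed. The aptamer transcript, which carries the RyhB terminator, was thus not detected at this gene. Its recovery on the column is not shown by these counts. The region that holds the 3′ external transcribed spacer of leuZ, between yecA and leuZ, had 102 and 15 reads, a ratio of 7.32 (4.24 to 13.6). Among housekeeping RNAs, 6S RNA (ssrS) had a ratio of 2.01 and RNase P RNA (rnpB) of 0.434.

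The aspartase gene aspA had 9865 reads in the aptamer library and 989 in the empty vector library, a ratio of 10.7 (10.1 to 11.5). The tryptophanase gene tnaA had a ratio of 4.08, the porin gene ompC of 4.19 and the ribonucleotide reductase gene nrdA of 15.3. In the other direction, treC of trehalose breakdown was 15.1-fold lower and galT of galactose breakdown 12.4-fold lower, while their operon partners treB and galK were 1.83-fold and 3.36-fold lower. The elongation factor gene tsf, downstream of rpsB, was 8.63-fold lower. Among rRNA copies, rrlD (3.74) and rrlG (3.71) stood apart from the other 23S genes. Across genes, which are not independent replicates, the log2 ratios of 1747 pairs of neighbouring genes had a Pearson r of 0.453, against at most 0.0939 in 10000 shuffles. Intergenic regions had a Pearson r of 0.882 with the mean of their flanking genes over 1083 regions.

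Most genes had a ratio above 1, 1979 of 2846 (69.5%), with a median log2 ratio of 0.67. With TMM and median-of-ratios scaling, which centre most genes near a ratio of 1 by construction, the median was -0.0994 and -0.0743, so the pattern holds for scaling by library totals. A few features that take many reads in the empty vector library could lower all other genes there. With rRNA genes and the 10 most abundant other features of each library out of the totals, the median log2 ratio was 0.673551. It stayed above 0, which argues against those features as the whole cause. Leaving out only rRNA and tRNA genes raised the median to 0.96. Against that value, taking out the abundant features as well lowered the median. Both of these totals sum listed features only, and with the sum of all listed features the median was 0.73. The closeness of 0.673551 to 0.67 thus joins shifts in opposite directions, and those features may be a part of the cause. A concentration spread over more genes stays open, since the 100 most abundant genes other than rRNA held 72.5% of such reads in the empty vector library and 51.3% in the aptamer library.

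The lowest ratios of the S10 operon were those of its first genes, from rpsJ to rplB. All its genes lay below the median ratio of all genes (1.59), the highest being rpmC at 1.16. With TMM scaling, which moved log2 ratios by -0.77, all of them fell below a ratio of 1. The highest ratio in the operon, at rpmC, was 43.4 times the lowest, at rplC, so a single ratio does not describe the whole operon. The operon and this comparison were chosen with these values known. The comparison is therefore no independent test of a difference in the level of the whole operon transcript. Retention of some RNA stretches by the coat protein without an aptamer, and uneven amplification of a few fragments, may each place reads at rplC, which held 56.4% of the operon's reads in the empty vector library. These cannot be told apart from read counts of 1 library per group, nor from a biological difference between the cultures, which was not tested.

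A candidate explanation for the small RNAs that were higher is that Hfq bound to the RyhB terminator brought them along. The 11 Hfq-binding small RNAs with 20 or more reads had a median ratio of 2.66 at the 94.4 percentile of matched random lists, inside the central 95% of random lists, and 8 stable RNAs not known to need Hfq a median ratio of 1.11 at the 26.4 percentile. The wider list set in advance, of small RNAs known to bind Hfq or to regulate other RNAs, had a median ratio of 1.46 at the 33.8 percentile. That list also holds RNAs not known to need Hfq, such as csrB and sibD. The Hfq-binding list was put together after the values had been seen, and the number of RNAs is small. The hypothesis therefore stays open, and no biological alternative was tested.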
